A study of Mus musculus with 22 samples.

How the data were processed

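RNA was measured in 22 mouse placentas, 1 labelled male and 1 labelled female from each of 11 litters. Per the labels' protocols, the non-decidual part of each placenta was dissected on gestational day 18, and total RNA was made into strand-marking libraries after removal of ribosomal RNA and sequenced as read pairs. The submitters' processing notes name Trimmomatic, HISAT2, HTSeq and DESeq2 and the mouse build mm10, without versions and without saying which step each tool did. The gene annotation and the strand setting of the counting are not given in the sources used here. For that reason reads of a gene and of a partner on the opposite strand may have been counted together, and genes that overlap others are uncertain. Members of near-identical families (the placental prolactins, the Psg genes, the granzymes, and C4a with its paralog) can also share reads.

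The authors deposited 1 file of raw read counts per library, with 25239 gene symbols in each and 0 rows that name no gene. A second deposited table holds a normalized signal, which is the authors' gene count divided by 1 size factor per library. Dividing each count by its normalized value gave the same factor for all genes of a library within 9.86e-08 percent. The third is the authors' table of 1 comparison, with 17116 adjusted p-values, deposited as log2 fold changes with p-values. Its standard errors and Wald statistics are scores as deposited. Which libraries and which model entered that comparison is not stated in its file. The table columns that matched no sample numbered 0.

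Groups were taken from the titles. The treatment row of the authors' normalized table differed from the title in 4 libraries, those of the litters Control 6 and EtOH 5, and the marks in the names of the count files matched that row in 22 of 22 libraries. The titles decided the main results, and each ethanol comparison was repeated with both litters exchanged. The sex row of the same table differed from the labels in 0 libraries. No library was relabelled from its values. Libraries whose sex-linked genes differed from their label were left out in repeats that were chosen after seeing the data.

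Because the dam received the gavage, the litter was the unit of treatment. Raw counts of the 2 siblings were added for the main ethanol comparison of 6 control and 5 ethanol litters. Ethanol was also compared in the 11 libraries labelled male and in the 11 labelled female. The sex difference was fitted on all 22 libraries with treatment as a covariate, and the difference of the ethanol effect between sexes as the interaction term. Each fit used edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr, robust quasi-likelihood tests and Benjamini-Hochberg adjustment at a false discovery rate of 0.05. DESeq2 1.42.0 was the other tool. Adjusted p-values of gene comparisons are edgeR's unless DESeq2 or the authors' table is named. CPM values of genes in the ethanol and sex comparisons use the TMM-scaled library sizes of the fit. CPM values of Xist, of the Y-linked sum, and of the yolk sac and chromosome 12 genes per library use total counts.

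A total of 28 gene lists and a list of sex chromosome genes were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Lists were tested with camera in limma 3.58.1 on voom log2 CPM of the summed litters with a preset correlation of 0.01, adjusted over the 28 lists. Camera with the correlation estimated per list and fry stand beside it. A list's level in a library is the mean log2 CPM of its members with a prior count of 1. The rule for named genes took genes past the false discovery rate by size of change. Where fewer than 5 passed in a direction, it took the 5 with the smallest p in that direction at a mean log2 CPM of at least 1, given as values only. It also took up to 4 members per list with the smallest p, all sex chromosome genes, and the 5 other genes with the largest sex difference in each direction. Positions are from the GENCODE annotation of GRCm38, the assembly that mm10 denotes, and are 1-based. Of 49 genes named for the comparisons, 48 had a position by symbol. Of these, 22 overlapped a gene on the opposite strand, 14 overlapped a gene on the same strand, and 26 overlapped any gene.

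Siblings of a litter form real pairs, since the litter row of the authors' normalized table gives 11 pairs that match the title numbers. Deviations from the group means correlated between siblings with a median r of 0.573 across 9839 genes (range -0.151 to 0.722, 8 of 11 pairs over 0.1), against a median of -0.141 for other pairs, and 13 of 22 libraries were closest to their sibling. The consensus correlation within litters was 0.366. The smallest mean chi-square per gene over 231 pairs of libraries was 25.4, so no pair of libraries agreed within sampling noise.

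Totals ran from 30.1 to 78.1M counts per library and from 85.2 to 137M per litter, and they limit the precision of genes under about 1 CPM most. On counts simulated for 18095 genes from the real means and library sizes, the litter test recovered 62% of 50 genes changed 1.5-fold, 90% of 50 changed 2-fold, and 100% at 4-fold and at 8-fold, with 9 unchanged genes among 185 calls. The test in males recovered 44%, 82%, 94% and 98% at those folds over 16798 genes. The test in females recovered 60%, 92%, 98% and 96% over 17172 genes, and the sex test recovered 76%, 92%, 100% and 100% over 17213 genes. A shift of 0.5 planted on the log2 scale in the endothelium list was found by camera with either correlation and by fry, with 1 list called by each. Changed genes were drawn from those with an expected count above 50 at the mean library size. These shares hold for such genes at the simulated spread. They do not include structure shared between genes, so the real tests may recover less.

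Alternatives were DESeq2's size factors, DESeq2's test, no filter and a stricter filter (at least 1 CPM in 5 libraries), the 20 most abundant genes left out, each litter left out in turn, the litters Control 6 and EtOH 5 left out or exchanged, the title number or the litter as a block, cell type lists as covariates, and placentas in place of litters. Correlations across samples were tested with 100000 permutations, and comparisons of list levels with exact permutation or exact sign-flip tests, all 2-sided. Transcript sequences of 4 genes were compared with BLAST 2.17.0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.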

Results

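Gene counts were obtained from 22 placentas of C57BL/6J mice, an inbred strain, to compare placentas after prenatal ethanol with placentas after water. Dams received ethanol or water by gavage on gestational day 10, and the non-decidual part of the placenta was collected on gestational day 18. There were 6 control and 5 ethanol litters, each with 1 placenta labelled male and 1 labelled female. Total counts were 30.1 to 61.4M in control males, 51.1 to 75.2M in control females, 40.5 to 59.1M in ethanol males and 53.7 to 78.1M in ethanol females, with a mean of 55.9 ± 10.4M (SD, n = 22, M standing for 10 to the power of 6). The labels name the litters Control 1 to Control 6 and EtOH 1 to EtOH 5. The treatment row of the authors' normalized table put Control 6 with the ethanol litters and EtOH 5 with the controls, against their titles, so each ethanol comparison is also given with both litters exchanged. In 3 libraries, those of Control 2 and the one labelled Control 5 female, sex-linked transcripts differed from the sex label, as described with the sex comparison.

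The first comparison asked which placental genes differed between ethanol and control litters, with the counts of the siblings added. The genes with the smallest p on the lower side were Sspn, which encodes sarcospan of the dystrophin-associated complex, the adenylyl cyclase Adcy1, the lincRNA D130009I18Rik, the low density lipoprotein receptor Ldlr, and Filip1l. Sspn was at 115 ± 25.4 CPM in control litters (SD, n = 6) and 63.9 ± 23.6 CPM in ethanol litters (SD, n = 5), a log2 fold change of -0.85 (SE 0.23). D130009I18Rik was at 111 ± 29.2 and 55.4 ± 26.1 CPM (log2 fold change -1.0, SE 0.30) and Filip1l at 366 ± 72.8 and 241 ± 70.3 CPM (log2 fold change -0.61, SE 0.19). Smaller differences were measured for Adcy1, at 11.1 ± 1.02 and 9.05 ± 1.02 CPM, and for Ldlr, at 91.5 ± 4.64 and 82.3 ± 4.37 CPM. On the higher side were Tc2n, the Ras exchange factor Rasgrp3, the cyclic AMP phosphodiesterase Pde4b, the transcription elongation factor Mllt3 and the lincRNA D5Ertd615e. Tc2n was at 19.4 ± 2.32 CPM in control and 24.9 ± 3.43 CPM in ethanol litters (log2 fold change 0.36, SE 0.10), and Rasgrp3 at 52.2 ± 4.18 and 61.4 ± 5.16 CPM (log2 fold change 0.24, SE 0.07). The log2 fold changes were 0.23 for Pde4b, 0.25 for Mllt3 and 0.35 for D5Ertd615e. None of these genes passed the test across all genes.

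Of 18095 genes tested with edgeR, 0 passed the false discovery rate of 0.05 (smallest adjusted p = 1), 212 had an unadjusted p under 0.05, and DESeq2 called 0 genes with 317 under that p. About 905 genes would be under an unadjusted p of 0.05 on average with no effect, if p-values were uniform. Dependence between genes does not change that mean but widens the spread of the count. With Control 6 and EtOH 5 exchanged, edgeR again called 0 genes and 572 had an unadjusted p under 0.05. The genes of smallest p were then others. They were Slc25a26 (log2 fold change 0.33, SE 0.07), the mitochondrial carrier of S-adenosylmethionine, with Pstpip1, Rsrp1, Nedd9 and Ccdc91 on the higher side. On the lower side they were the recombination gene Rad54l (-0.50, SE 0.11), the glucocorticoid receptor cochaperone Fkbp5 (-0.49, SE 0.11), the double-stranded RNA kinase Eif2ak2 (-0.18, SE 0.04), Poln and Itih5. Under that exchange the log2 fold change of Sspn was -0.23, of D130009I18Rik -0.26, of Filip1l -0.15, of Adcy1 -0.21 and of Ldlr -0.11. On the higher side it was 0.09 for Tc2n, 0.12 for Rasgrp3, 0.066 for Pde4b, 0.25 for Mllt3 and 0.27 for D5Ertd615e.

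Sspn lies on chromosome 6 (145931641 to 145965223), D130009I18Rik on chromosome 14 (104612791 to 104966783), Filip1l on chromosome 16 (57353093 to 57573126), Adcy1 on chromosome 11 (7063489 to 7178506) and Ldlr on chromosome 9 (21723483 to 21749919) of GRCm38. Tc2n lies on chromosome 12 (101645443 to 101718523), Rasgrp3 on chromosome 17 (75435896 to 75529054), Pde4b on chromosome 4 (102087543 to 102607259), Mllt3 on chromosome 4 (87769925 to 88033364) and D5Ertd615e on chromosome 5 (45009171 to 45424402). Several overlap an annotated gene on the opposite strand, Sspn with Sspnos, Filip1l with Cmss1, Tc2n with Gm16285, D130009I18Rik with Gm25724, Slc25a26 with Lrig1 and Rad54l with Lrrc41. Their counts are uncertain to the extent that the counting did not use strand.

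**Figure D1:**
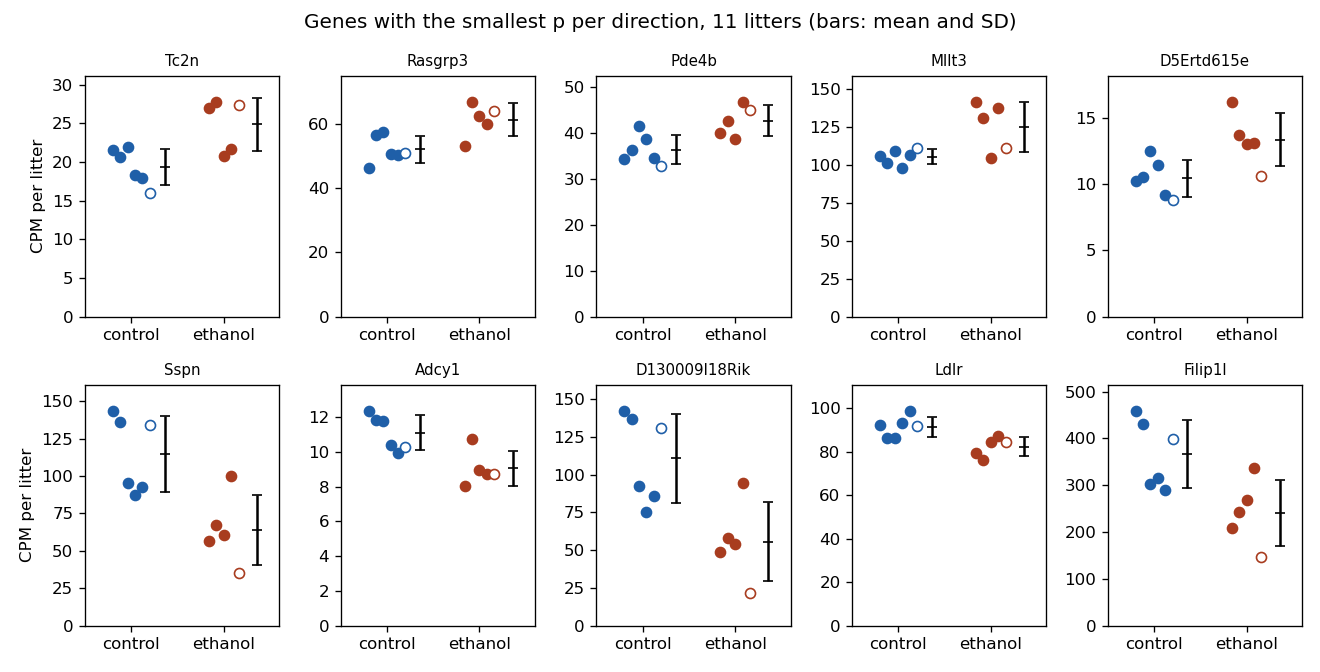
CPM per litter (vertical axis of each panel) of the 5 genes with the smallest p on the higher side (upper panels) and on the lower side (lower panels), in 6 control and 5 ethanol litters; points are litters, open circles are Control 6 and EtOH 5, and bars give the mean and SD. The groups of each gene overlap: Sspn had means of 115 and 63.9 CPM, and none of the 10 genes passed the test across all genes.

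In placentas labelled male, Sspn (log2 fold change -0.98, SE 0.33) and D130009I18Rik (-1.13, SE 0.41) were among the 5 genes of smallest p on the lower side, with Ahsg, Mitd1 (-0.20) and the splicing factor gene Sf3b4 (-0.18). The male libraries are part of the litter sums, so this is no second observation of Sspn and D130009I18Rik. Neither was among the 5 genes of smallest p on the lower side in females. Sspn was at 118 ± 38.3 CPM in control males (SD, n = 6) and 59.7 ± 32.9 CPM in ethanol males (SD, n = 5). Ahsg, which encodes the plasma protein fetuin-A, averaged 25.6 ± 60.3 CPM in control males because the library labelled Control 3 male had 148 CPM, against 0.692 ± 0.461 CPM in ethanol males. On the higher side were the small Cajal body RNA Scarna2 (0.48, SE 0.13), the phosphoinositide phosphatase Inpp4b (0.23), the mismatch repair gene Msh2 (0.21), the complement gene C4a (0.36) and the dermatan sulfate epimerase Dse (0.18). Among 16798 genes edgeR called 0 (smallest adjusted p = 1) with 122 under an unadjusted p of 0.05, and DESeq2 called 0 with 226. Exchanging both litters gave 0 calls and 411 genes under that p. The log2 fold changes were then -0.35 for Sspn, -0.35 for D130009I18Rik, -0.11 for Mitd1, -0.12 for Sf3b4, 0.17 for Scarna2, 0.087 for Inpp4b, 0.073 for Msh2, 0.18 for C4a and 0.19 for Dse.

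In placentas labelled female, the genes of smallest p on the higher side were Rasgrp3, at 51.8 ± 6.09 CPM in control (SD, n = 6) and 65.7 ± 3.86 CPM in ethanol females (SD, n = 5), the mitochondrial thiolase Acaa2 (log2 fold change 0.23, SE 0.06), Mllt3 (0.26, SE 0.08), Phxr4 (0.36) and the endothelial adhesion gene Pecam1, at 151 ± 14.2 and 177 ± 10.2 CPM. On the lower side were Syvn1, a ubiquitin ligase of endoplasmic reticulum protein degradation (-0.27, SE 0.08), the complement receptor C3ar1 (-0.45, SE 0.13), the germ cell gene Asz1 (-0.84), the interferon-induced Oas3 (-0.52) and Anks1b (-0.34). Among 17172 genes edgeR called 0 (smallest adjusted p = 1) with 372 under an unadjusted p of 0.05. DESeq2 called 2, the Y-linked Eif2s3y and Uty, with 555 genes under that p. In the control group the counts of these genes came mostly from the libraries labelled Control 2 female and Control 5 female. Without them DESeq2 called 0 genes with 478 under that p, and edgeR 0 with 294. Exchanging both litters gave 0 edgeR calls and 800 genes under that p. The log2 fold changes were then 0.24 for Rasgrp3 (0.34 by the titles), 0.11 for Acaa2, 0.25 for Mllt3, 0.32 for Phxr4, 0.14 for Pecam1 (0.23 by the titles), -0.14 for Syvn1, -0.34 for C3ar1, -0.57 for Asz1, -0.32 for Oas3 and -0.19 for Anks1b.

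The test of whether the ethanol effect differed between sexes named the Y-linked Uty, Ddx3y, Kdm5d and Eif2s3y, the Wnt receptor gene Fzd8 (difference of log2 fold changes, males against females, 0.36, SE 0.11), and on the lower side Exosc1 (-0.22), Kdm8 (-0.32), Nemf (-3.38, SE 1.19), Rps27a (-0.55, a ribosomal protein gene) and the predicted gene 9430083A17Rik (-0.53). The values of the Y-linked genes depended on the 3 control libraries whose sex label did not match, and with these left out the values were 1.58 for Uty (SE 0.45), -0.15 for Ddx3y (SE 0.84), -3.21 for Kdm5d (SE 1.21) and 1.96 for Eif2s3y (SE 1.76). These rest on few counts in females. Kdm5d had 0 counts in the 4 remaining control females and at most 3 in an ethanol female, and Eif2s3y had 2 and 0 counts in all. Nemf was at 8730 CPM in the library labelled EtOH 4 female and at most at 772 CPM in the other ethanol females, and its value was -1.20 without EtOH 4. None passed edgeR's test (0 of 17463 genes, 154 under an unadjusted p of 0.05), and DESeq2 called 1, Eif2s3y, with 271 under that p, and 0 without those 3 libraries (212 under that p). With both litters exchanged edgeR called 0 genes with 248 under that p. The values were then 0.26 for Fzd8, -0.12 for Exosc1, -0.16 for Kdm8, -3.32 for Nemf, -0.19 for Rps27a and -0.27 for 9430083A17Rik. Across 16749 genes, which are not independent replicates, the log2 fold changes in males and in females correlated at r = 0.036 by the titles and at r = 0.300 with both litters exchanged. The males and females are siblings of the same litters, so differences among litters alone can give a positive r.

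Among 28 gene lists tested between ethanol and control litters, the endothelium list had the smallest p. Of its 24 genes, 22 had a positive log2 fold change in edgeR, and the median in the voom fit was 0.17. The junction gene Pecam1 was at 152 ± 14.9 CPM in control (SD, n = 6) and 173 ± 6.30 CPM in ethanol litters (SD, n = 5), the tight junction gene Cldn5 at 6.94 ± 0.448 and 7.86 ± 0.707 CPM, and the clotting factor gene Vwf at 32.6 ± 3.84 and 39 ± 8.29 CPM. The log2 fold change of Egfl7 was 0.23 (SE 0.12). Related lists shifted in the same direction by less. Angiogenic factors and receptors had a median of 0.062 (24 of 38 positive), with Angpt2 at 0.21 (SE 0.08), Apln at 0.23, Tie1 at 0.20 and Angpt1 at 0.21. Vasoactive signalling had a median of 0.044 (24 of 39 positive), with the endothelin gene Edn1 at 0.37 (SE 0.13), Calcrl at 0.28, Ptgs1 at 0.20 and the arginase gene Arg2 at -0.30. The endothelium list shares 5 genes with other lists. Camera's adjusted p was 1.64e-08 for endothelium, 0.0114 for the angiogenic list and 0.0407 for the vasoactive list, and adjusted p = 0.893 with an estimated correlation for each. With both litters exchanged the endothelium median was 0.093 (21 of 24 positive, camera adjusted p = 0.0272, and adjusted p = 0.872 with an estimated correlation), and the other 2 camera calls were lost (0.137 and 0.563). The mean level of the endothelium list stood apart in Control 1 female (3.94 log2 CPM) and EtOH 1 male (3.79). The smooth muscle and pericyte list was at 3.92 and 3.40 in these libraries, and the labyrinth list at 4.79 and 4.31. Without Control 1 the endothelium median was 0.071, with the call kept. With 1 litter left out the angiogenic call was lost in 5 of 11 runs and the vasoactive call in 7 of 11 (lowest medians 0.030 without Control 1 and 0.026 without Control 4).

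The interferon response list was shifted down, with 21 of 24 genes negative and a median log2 fold change of -0.069 (camera adjusted p = 0.00043, and adjusted p = 0.893 with an estimated correlation). The transcription factor genes Stat2, at 50.7 ± 2.18 CPM in control (SD, n = 6) and 46.4 ± 2.97 CPM in ethanol litters (SD, n = 5), and Stat1 (-0.08, SE 0.05), with Zbp1 (-0.27, SE 0.17) and Isg15 (-0.17), had the smallest p. The median was -0.099 with both litters exchanged, with a camera adjusted p of 2.12e-05, and adjusted p = 0.872 with an estimated correlation. By the titles the camera call was lost without Control 3 (0.158) or without EtOH 4 (0.0612), and the median was -0.032 without Control 1. Nutrient transporters were shifted up, with 26 of 35 positive and a median of 0.061 (camera adjusted p = 0.0331, and adjusted p = 0.893 with an estimated correlation). Among them the folate transporter Slc46a1 was at 0.08 (SE 0.05), the fatty acid transporter Slc27a1 at 0.09, the glucose transporter Slc2a3 at 0.15 and the prostaglandin transporter Slco2a1 at -0.16. That call was lost in 6 of 11 runs that left out 1 litter, with the lowest median, 0.021, without Control 1.

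Markers of visceral endoderm and yolk sac, a fetal membrane next to the placenta, had the largest median, 0.86 (11 of 15 positive, camera adjusted p = 0.00423, and adjusted p = 0.893 with an estimated correlation). That median is of the voom fit, and the edgeR log2 fold changes of single genes given below are smaller. The list varied over 5.87 log2 units among libraries. Its genes of smallest p were the retinol carrier Rbp4 (-0.22), Amn (0.27, SE 0.78), the receptor Cubn (0.28, SE 0.82) and the apolipoprotein Apob, at 918 ± 1454 CPM in control (SD, n = 6) and 1137 ± 946 CPM in ethanol litters (SD, n = 5). When both litters were exchanged the median turned to -0.60 (15 of 15 negative, camera adjusted p = 0.00676, and adjusted p = 0.872 with an estimated correlation), and without both litters it was 0.069 with a camera adjusted p of 0.828. The call was also lost without Control 4 (0.142), Control 6 (0.199) or EtOH 5 (0.249) alone. The median ran from 0.43 without Control 6 to 1.38 without Control 5 when 1 litter was left out.

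Of the other lists, 0 passed camera. Among placental and maternal cell types, medians were 0.079 for labyrinth syncytiotrophoblast (14 of 18 positive, with the fusion gene Syna at -0.27, Tfeb at 0.11, Ly6e at -0.07 and the lactate transporter Slc16a3 at 0.17), -0.023 for spongiotrophoblast and glycogen cells (with Ascl2 at 0.33, Psg18 at -0.16 and Prl7a2 at -0.19), -0.020 for trophoblast giant cells (12 of 15 negative, with Hand1 at -0.13, Ccne1 at -0.23, Prl4a1 at 0.18 and Lgals3 at 0.05), and -0.089 for decidual stroma (with Igfbp3 at 0.30, Erv3 at -0.26 and Gja1 at -0.13). The median was 0.32 for uterine natural killer and T cells (with the granzymes Gzmb at 0.84, Gzmf at 0.69, Gzmc at 0.69 and Gzmg at 0.66). Medians were -0.046 for macrophages (C1qb at -0.13), 0.00011 for neutrophils (Ngp at -1.53, Lcn2 at 0.46), -0.045 for erythroid cells (Hemgn at -0.98, Rhag at -0.73, Epb42 at -0.24) and 0.093 for smooth muscle and pericytes (Notch3 at 0.20, Actg2 at 0.48, Cnn1 at 0.39). With both litters exchanged 10 lists passed camera. They included spongiotrophoblast (0.091), uterine natural killer and T cells (0.80), erythroid cells (0.35), hypoxia response (0.091), unfolded protein response (0.073) and nutrient transporters (0.068) on the higher side and cholesterol synthesis (-0.053) on the lower side. With an estimated correlation camera's adjusted p was 0.872 for each of the 10.

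Stress and metabolic lists lay close to 0. Medians were 0.024 for hypoxia response (Mxi1 at 0.15, Car9 at -0.35), -0.031 for ethanol and acetaldehyde metabolism (the alcohol dehydrogenases Adh1 at -0.37 and Adh5 at -0.06, and Aldh1a1 at 0.44), -0.015 for oxidative stress defence (Mgst1 at 0.25, Gpx4 at -0.08), 0.0014 for the unfolded protein and integrated stress response (Sesn2 at -0.14, Herpud1 at -0.12), -0.044 for immediate early genes (19 of 25 negative, Zfp36 at -0.10, Fosb at -0.18) and -0.076 for cytokines and chemokines (Tgfb1 at -0.11, Il33 at 0.30). They were 0.033 for imprinted genes (Zdbf2 at 0.15, Igf2r at 0.08, Tspan32 at -0.28), -0.032 for cell cycle (Plk1 at 0.21, E2f1 at -0.20), -0.031 for collagens and extracellular matrix (Col6a3 at -0.45, Postn at 0.22), -0.020 for cholesterol and fatty acid synthesis (20 of 26 negative, Ldlr at -0.15, Idi1 at -0.26), -0.0084 for nuclear oxidative phosphorylation (Cox5a at -0.08, Uqcrb at -0.04), -0.030 for ribosomal proteins (Rps11 at -0.08, Rps2 at -0.11) and -0.0036 for DNA methylation and chromatin enzymes (Sirt1 at 0.13, Ezh2 at -0.11, Tet3 at 0.09). In neutrophils and in the unfolded protein response the median was above 0 while the mean and camera's direction were below it. Members past the false discovery rate numbered 0 over all genes and 0 adjusted over the list alone.

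**Figure D2:**
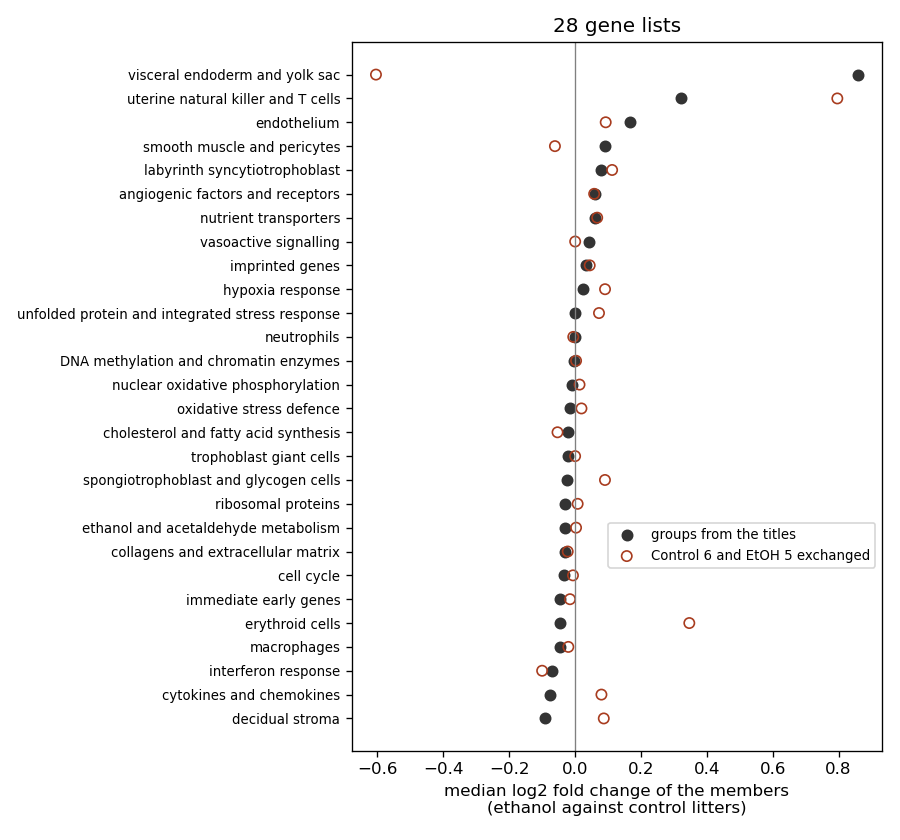
Median log2 fold change of the members of each of 28 gene lists, ethanol against control litters (horizontal axis), with groups from the titles (filled) and with Control 6 and EtOH 5 exchanged (open). By the titles 25 of 28 medians lie within 0.1 of 0, and the yolk sac list moves from 0.86 to -0.60 when the litters are exchanged.

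Mean list levels per litter were also compared by an exact permutation test over all 462 splits of the 11 litters. Endothelium was at 4.56 ± 0.244 log2 CPM in control (SD, n = 6) and 4.71 ± 0.187 in ethanol litters (SD, n = 5), and decidual stroma at 5.78 ± 0.213 and 5.72 ± 0.246. Spongiotrophoblast was at 8.03 ± 0.141 and 8.01 ± 0.224, and the yolk sac list at 4.98 ± 1.44 and 5.58 ± 0.951. None of 11 cell type lists differed in the exact test (adjusted p = 0.922 for each, and 0.831 with both litters exchanged).

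**Figure D3:**
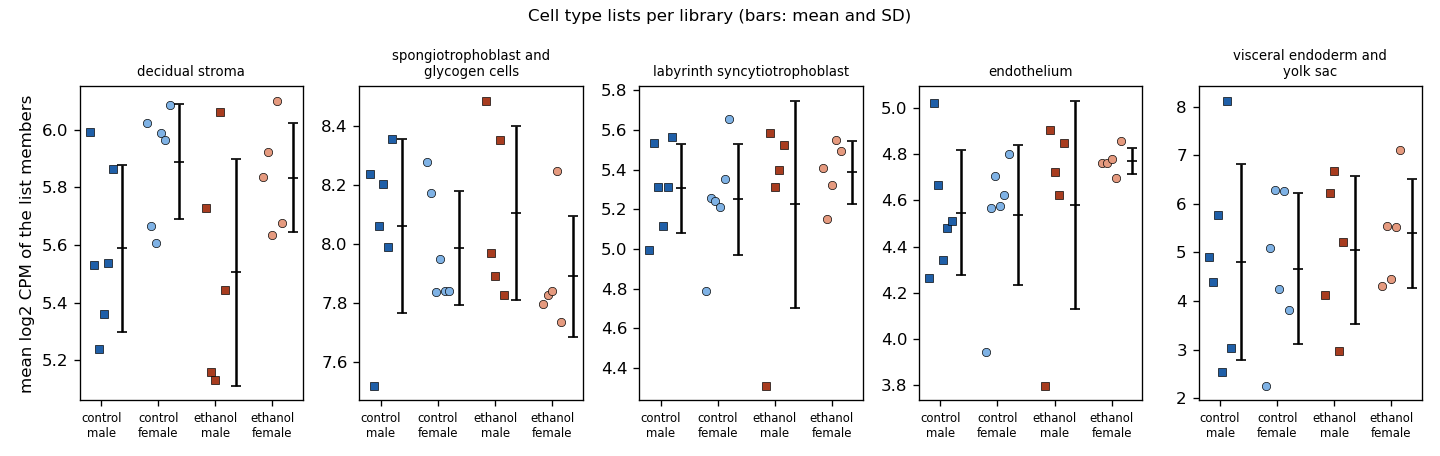
Mean log2 CPM of the members of 5 cell type lists (vertical axes) in each of 22 libraries by treatment and labelled sex; points are libraries and bars give the mean and SD. The endothelium list had its lowest levels in EtOH 1 male (3.79) and Control 1 female (3.94), and the yolk sac list spanned 5.87 log2 units.

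The authors' deposited table of an ethanol comparison listed 39 genes with an adjusted p under 0.05, 12 higher and 27 lower, with log2 fold changes of 0.105 to 0.425 in size (median 0.262). In the authors' deposited table the smallest adjusted p belonged to Slc25a26 (log2 fold change 0.30, adjusted p = 0.000219) and Eif2ak2 (-0.19, adjusted p = 0.000436). The same deposited table lists the RNA polymerase III subunit Polr3b (0.12), Fkbp5 (-0.39), the DNA demethylase Tet3 (0.12), Zscan25 (-0.28), Pstpip1 (0.32), Rad54l (-0.38), the amino acid stress kinase Eif2ak4 (-0.19) and malic enzyme Me1 (0.22). In the litter fit by the titles all 39 had the same sign, and 3 had an unadjusted p under 0.05. With both litters exchanged all 39 had the same sign, and 39 had an unadjusted p under 0.05, with 0 past edgeR's false discovery rate. Across 18095 genes, which are not independent replicates, the Wald statistic of the authors' deposited table correlated with the litter fit at r = 0.529 by the titles and at r = 0.988 with both litters exchanged. Slc25a26 lies on chromosome 6 (94500331 to 94604672), Eif2ak2 on chromosome 17 (78852564 to 78882573) and Fkbp5 on chromosome 17 (28399094 to 28517527).

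The sex comparison first showed that 3 libraries did not match their label. In the 10 libraries labelled male other than Control 2, the X-inactivation transcript Xist was at 187 ± 108 CPM (SD, n = 10) and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 200 ± 25.1 CPM. In the 9 libraries labelled female other than Control 2 and Control 5, Xist was at 1302 ± 96.7 CPM (SD, n = 9) and the Y-linked sum at 0.144 ± 0.119 CPM. The library labelled Control 2 male had 1241 CPM of Xist and a Y-linked sum of 0.105 CPM, and the library labelled Control 2 female had 169 CPM of Xist and a Y-linked sum of 224 CPM. The library labelled Control 5 female had 962 CPM of Xist and a Y-linked sum of 64.1 CPM.

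**Figure D4:**
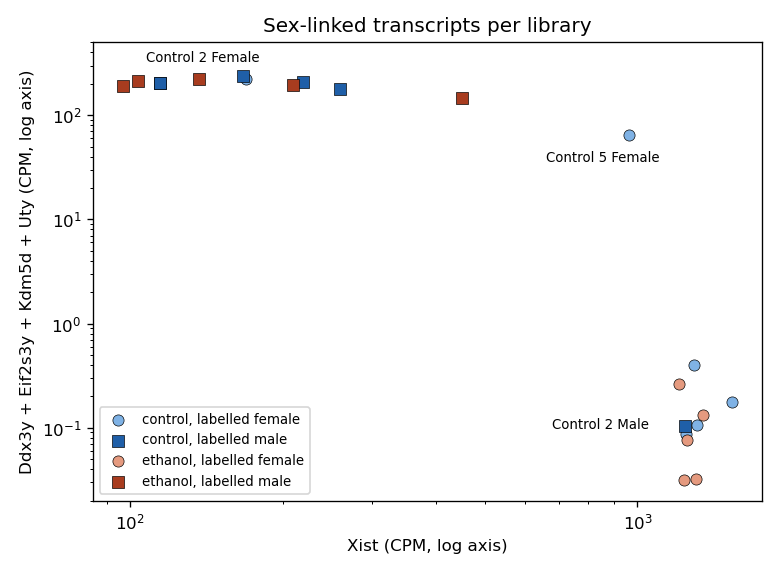
Xist (horizontal log axis, CPM) against the summed CPM of 4 Y-linked genes (vertical log axis) in 22 libraries; squares are labelled male, circles female. Control 2 female lies with the males at 224 CPM, Control 2 male with the females at 0.105 CPM, and Control 5 female between them at 64.1 CPM.

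Between the labelled sexes in all 22 libraries, edgeR called 0 of 17213 genes, with the smallest adjusted p = 0.0601 for the X-linked Eif2s3x (log2 fold change, males against females, -0.34, SE 0.06) and Taf1 (-0.40, SE 0.07). There were 1231 genes with an unadjusted p under 0.05, and DESeq2 called 39 genes, 10 higher in males and 29 in females. With the litter as a block edgeR called 40, 2 higher in males and 38 in females. By the labels the log2 fold changes were -2.08 for Xist, -0.29 for Kdm5c, -0.24 for Kdm6a, 0.05 for Ddx3x, -0.09 for Tsix, 4.21 for Uty, 4.02 for Ddx3y, 3.86 for Kdm5d, 3.66 for Eif2s3y, 3.05 for Usp9y and 1.54 for Zfy1.

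Without both libraries of Control 2 and without Control 5 female, a set chosen after seeing the data, edgeR called 24 genes, 9 higher in males and 15 in females. Of these 8 were Y-linked and all higher in males, 13 were X-linked and all higher in females, 2 were autosomal and 1, Vamp7, had no position. Xist was at 191 ± 118 CPM in males (SD, n = 10) and 1297 ± 126 CPM in females (SD, n = 9) (log2 fold change -2.76, SE 0.27, edgeR adjusted p = 8.94e-06). The X-linked genes with higher levels in females included the translation factor gene Eif2s3x (-0.42, SE 0.03), the transcription factor gene Taf1 (-0.51, SE 0.04), the O-GlcNAc transferase Ogt (-0.56, SE 0.06), the histone demethylases Kdm5c (-0.39) and Kdm6a (-0.30), Pin4 (-0.49), Upf3b (-0.28) and the lncRNAs Jpx (-0.43) and Ftx (-0.24). Uty was at 94.5 ± 9.93 CPM in males and 0.0858 ± 0.0783 CPM in females, Ddx3y at 61.6 ± 6.43 and 0.0447 ± 0.0492, Kdm5d at 23.8 ± 3.97 and 0.00938 ± 0.0179, and Eif2s3y at 21.1 ± 8.30 and 0.00365 ± 0.0110. The autosomal genes were Ncald, a calcium sensor gene (0.41, SE 0.07, edgeR adjusted p = 0.0196), and the carboxypeptidase Cpq (-0.32, SE 0.06, edgeR adjusted p = 0.0378), both on chromosome 15 (37366175 to 37792570 and 33083129 to 33594552). The X-linked Ddx3x (0.05) and Tsix (-0.14) did not pass.

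With siblings compared within litters, that is with the litter as a block and without the litters Control 2 and Control 5, edgeR called 103 genes, 25 higher in males and 78 in females. Of these 75 were autosomal, 18 higher in males and 57 in females, and Ncald and Cpq were not among them. Cell type lists also differed between siblings, with decidual stroma lower in the male in 10 of 10 litters (-0.33 log2 CPM), over the litters other than Control 2. The spongiotrophoblast (0.22) and giant cell (0.20) lists were higher in the male in 9 of those 10. The 19 X-linked genes were all higher in females and included the 13 called without the block, and the 7 Y-linked genes were all higher in males. The autosomal genes of smallest p included the secretin gene Sct (log2 fold change 0.33, SE 0.043, edgeR adjusted p = 0.0114), the acid phosphatase Acp5 (0.50, SE 0.066) and the placental prolactin family gene Prl2c5 (0.42, SE 0.067) on the male side. On the female side they included the lysophosphatidic acid receptor Lpar1 (-0.53, SE 0.072, edgeR adjusted p = 0.0155), Nav3 (-0.49, SE 0.069) and Pla2r1 (-0.71, SE 0.11). These autosomal genes were chosen after their values were seen, and 3 of the 75 belonged to the fixed lists: Ezh2 (0.19), Aldh1a2 (-1.28) and the decidual Hand2 (-0.50). With the block and all 22 libraries, 36 of 40 called genes were autosomal.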

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

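All tests in this part were chosen after the results they bear on had been seen. Among 140 groups of 5 or 6 libraries or litters, 16 had a highest or lowest value set apart from the rest by Dixon's rule, and chance gives about 5% of groups.

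Sex-linked transcripts of 3 control libraries differed from the sex label: the library labelled Control 2 male had Xist at 1241 CPM and a Y-linked sum of 0.105 CPM, each apart from the other control males, and the Y-linked sum of 224 CPM in the library labelled Control 2 female was apart from the other control females. The Control 2 library labelled female lay inside the range of the 10 other libraries labelled male (146 to 237 CPM for the Y-linked sum) and the one labelled male inside that of 9 females (0.0317 to 0.397 CPM), which is consistent with the siblings' labels being exchanged. For Control 5 female, the Y-linked sum of 64.1 CPM lay below every male, which argues against a male placenta under a female label. Each of 4 Y-linked genes stood at 24.8 to 29% of the level in its brother, with a CV of 6.39%, the lowest against any of 11 libraries with Y-linked counts (the next was 19.8%). RNA of the brother in the female library is therefore a candidate explanation, and that share predicts 997 CPM of Xist where 962 CPM was measured. Other genes were mixed. Zfy1, at 0.40 CPM against 1.39 CPM in the brother, was near that share. Usp9y, with 1 count against 22 in the brother, and Afp, at 1485 CPM against 7013 CPM, were below it. Whether RNA of the brother entered at dissection or during library preparation stays open, and no biological explanation was tested.

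Sspn at 117 CPM and D130009I18Rik at 111 CPM in EtOH 4 male were apart from the other ethanol males (at most 54.0 and 47.5 CPM). Over 11 litters Sspn correlated with D130009I18Rik (r = 0.994, rho = 1), Filip1l (r = 0.978, rho = 0.964) and Zc3h7a (r = 0.949, rho = 0.955), each with a permutation p of 1e-05 for r, the smallest that the permutations can give, adjusted to 0.0428 over 12833 genes, and r without the 2 litters farthest in Sspn was 0.996, 0.945 and 0.931. Differences between siblings, which share the treatment, correlated as well over 11 litters (r = 0.983, 0.960 and 0.927, rho = 0.982, 0.973 and 0.955, largest permutation p = 3e-05 for r and 4e-05 for rho, adjusted p at most 3e-05 over 3 genes picked for their correlation over all placentas, which already holds these differences, and r = 0.965, 0.909 and 0.840 without the 2 farthest). The genes thus moved together without a difference in treatment, which argues against ethanol as the whole cause of the joint movement. These differences do not tell whether ethanol also shifted the genes between litters. The genes lie on chromosomes 6, 14, 16 and 16, and the longest stretch shared at 95% identity among 28 transcripts of the 4 genes was 50 bases, which argues against reads shared through sequence, and r of Sspn with the decidual stroma list was 0.453 (permutation p = 0.159, rho = 0.5, p = 0.123, and r = 0.397 without the 2 farthest), which argues against the share of decidual tissue as the whole of it. A regulatory link, a transcript in common with an unannotated insertion, and another cell type stay open as untested, and the ethanol effect on the level of Sspn did not pass edgeR's test (log2 fold change -0.82 with the decidual list as a covariate).

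The remaining values are given without explanation. The mean log2 CPM of the endothelium list was 3.94 and of the smooth muscle and pericyte list 3.92 in Control 1 female, below the other control females (at least 4.57 and 4.58). In EtOH 1 male the labyrinth syncytiotrophoblast list was at 4.31 and the endothelium list at 3.79, below the other ethanol males (at least 5.31 and 4.62). The macrophage list was at 2.11 in EtOH 4 male, below the other ethanol males (at least 2.68). The spongiotrophoblast and glycogen cell list was at 8.25 in EtOH 4 female, above the other ethanol females (at most 7.84). Ahsg was at 148 CPM in Control 3 male and at most at 3.35 CPM in the other control males. Asz1 was at 2.09 CPM in EtOH 1 female and at most at 1.39 CPM in the other ethanol females. Exosc1 was at 10.7 CPM in EtOH 2 male, above the other ethanol males (at most 9.93), and at 9.33 CPM in EtOH 4 female, below the other ethanol females (at least 10.4). Nemf was at 8730 CPM in EtOH 4 female and at most at 772 CPM in the other ethanol females.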

How the results depend on the processing

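The alternatives that leave out Control 2 and Control 5 (or Control 5 female) together, use the yolk sac list as a covariate, use DESeq2 on all placentas, or join 2 choices were added after the data were seen, and the cause of the changes below was not tested unless stated. In edgeR the ethanol comparisons of litters, males and females and the interaction gave 0 genes under every alternative run, with unadjusted counts of 155 to 367 (litters, highest without EtOH 1), 111 to 267 (males, highest without EtOH 1), 304 to 693 (females, highest without EtOH 4, 604 without Control 6) and 137 to 189 (interaction) when 1 litter was left out. DESeq2 gave 0 in litters and males, 2 in females and 1 for the interaction (0 and 0 without Control 2 and Control 5 female), and 46 genes (14 higher, 32 lower) on 22 placentas as if independent with both litters exchanged, against 0 by the titles. Depth limits the precision of genes near 1 CPM, where the unfiltered tests add low counts but no calls.

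Sex calls, 0 by the labels, were 39 with DESeq2, 2 (Eif2s3x and Taf1) with the stricter filter and 2 without the 20 most abundant genes, 24 without Control 2 and Control 5 female, 9 in ethanol placentas alone and 0 in control placentas alone. They were 0 to 31 with 1 litter left out, 31 without Control 2. With the litter as a replicate block 40 genes passed, and 103 with the block and without Control 2 and Control 5. The block changed no call of the interaction (0 genes). Gene lists, 6 by the titles, were 0 with an estimated correlation, 0 with fry, 10 with both litters exchanged (0 with an estimated correlation), 10 without the litters Control 2 and Control 5, and 2 to 14 with 1 litter left out (14 without Control 2, 2 without Control 4, 11 without EtOH 1, 3 without EtOH 5). The endothelium call was kept in 11 of 11 such runs (largest adjusted p = 0.00233, medians 0.071 without Control 1 to 0.21 without EtOH 1), the interferon call in 9, yolk sac in 8, angiogenic in 6, nutrient transporters in 5 and vasoactive in 4. The deposited table has 11 genes at an adjusted p of 0.01 in place of 39.

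The labels give control and ethanol litters with the same number no shared origin. Their deviations correlated at -0.032 to 0.587 (median 0.363, against -0.103 for 25 other pairs), with 4 of 5 over 0.1 and 2 of 10 litters closest to their own number, so a shared origin stays open. With the number as a replicate block, 10 lists passed and the ethanol gene counts stayed at 0.

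For named genes, 2926 of 2961 log2 fold changes in litters, 229 of 229 in males and 240 of 240 in females kept their direction and side of the threshold. These genes were picked by p in the same libraries and lay far from the threshold, so such counts say little about robustness. For the sex difference 96 of 566 became calls and 1 reversed, and for the interaction 4 of 210 reversed. With both litters exchanged these turned: Ly6e 0.016, Psg18 0.16, Prl7a2 0.23, Ccne1 0.0079, Igfbp3 -0.071, Gja1 0.098, Epb42 0.13, Amn -0.80, Cubn -0.93, Apob -1.10, Actg2 -0.11, Cnn1 -0.26, Apln -0.063, Gpx4 0.013, Herpud1 0.048, Stat1 0.0093, Tspan32 0.053, E2f1 0.068, Col6a3 0.31, Uqcrb 0.023 and Rps2 0.035, and the list medians of spongiotrophoblast 0.091, erythroid cells 0.35, yolk sac -0.60 and unfolded protein response 0.073, as judged with camera's direction. Without both litters Prl7a2 was 0.015, Amn -0.32, Cubn -0.41 and Apob -0.50, and the yolk sac median 0.069 with camera's direction down. With 1 litter left out, values ran from -1.16 to 0.33 for Hemgn and -0.90 to 0.15 for Rhag (both highest without Control 3), from -0.0077 (without EtOH 1) to 0.099 for Lgals3, and from -0.049 (without EtOH 2, and -0.0072 without EtOH 4) to 0.34 for Prl4a1. They ran from -0.10 to 1.39 for Amn, -0.20 to 1.47 for Cubn and -0.26 to 1.74 for Apob (each lowest without EtOH 5 and highest without Control 5), and C1qb was 0.0079 without Control 5. With the yolk sac list as a covariate Cnn1 was -0.032 and the median of that list -0.090, as its own covariate. Tsix was 0.016 in the sex difference without EtOH 1. In the interaction without Control 2 and Control 5 female, Ddx3y was -0.15 and Kdm5d -3.21, and with the litter block -0.14 and -3.24.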

Other observations

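The comparisons of cell type lists between sexes, the test of Xist in males, the comparison among litters and the tests of the deposited comparison were chosen after the data had been seen, while the measure and bound of the counts of other splits were fixed before those counts were seen. Cell type lists differed between siblings labelled male and female within litters. Over the 10 litters other than Control 2, decidual stroma was lower in the male in 10 of 10 litters (mean difference, male minus female, -0.33 log2 CPM, exact sign-flip p = 0.00195) and the list of uterine natural killer and T cells in 9 of 10 (-0.47, exact p = 0.00781). The spongiotrophoblast and glycogen cell list was higher in the male in 9 of 10 litters (0.22, exact p = 0.00391) and the trophoblast giant cell list in 9 of 10 (0.20, exact p = 0.00586). The adjusted p over 11 lists was 0.0215 for each of these 4, and without Control 5 it was 0.0286 for decidual stroma, spongiotrophoblast and giant cells and 0.0430 for uterine natural killer and T cells in the exact tests (n = 9). The other 7 lists did not pass, among them endothelium (-0.13, lower in 8 of 10) and labyrinth syncytiotrophoblast (-0.075, lower in 6 of 10). The most abundant members were Prl8a2 (361 to 1038 CPM), Htra3 (197 to 531 CPM) and Erv3 (140 to 517 CPM) in the decidual list, Il2rb (23.5 to 62.2 CPM) in the killer cell list, Tpbpa (4565 to 9413 CPM) and Psg21 in the spongiotrophoblast list and Prl3b1 (5214 to 7403 CPM) and Ctsj in the giant cell list. The decidual list holds 2 genes of other lists, and 19 of its 20 members averaged over 1 CPM here. The killer cell list holds 0 genes of other lists, and only 9 of its 18 members averaged over 1 CPM. The spongiotrophoblast list holds 3 genes of other lists (20 of 21 members over 1 CPM) and the giant cell list 1 (15 of 15).

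Litters of the same treatment differed in many genes. With sex and treatment in the model, 1940 of 18105 genes differed among litters at edgeR's false discovery rate (6237 with an unadjusted p under 0.05), 88 of them members of the gene lists. The ranges below run over litters of both treatments. The predicted gene Gm10130 ranged from a litter mean of 9.25 CPM in EtOH 1 to 22.3 CPM in Control 2 (adjusted p = 4.41e-06, largest gap between siblings 2.03 CPM). Med26, a Mediator subunit, ranged from 39.8 CPM in Control 3 to 65.8 CPM in EtOH 3 (largest gap 5.94 CPM). Pi15 ranged from 1.596 CPM in Control 2 to 18.0 CPM in EtOH 4 (largest gap 10.0 CPM). Atp8a1, a phospholipid flippase, ranged from 56.5 CPM in EtOH 3 to 142 CPM in Control 6 (largest gap 23.3 CPM). The linker histone genes H1f4 and H1f2 ranged from 8.14 to 35.2 CPM and from 33.5 to 72.7 CPM, with the lowest mean in EtOH 1 and the highest in EtOH 5 for both. EtOH 5 stands with the controls in the authors' treatment row.

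Among the 11 cell type lists, yolk sac markers had the largest range over libraries (5.87 log2 units). Afp ranged from 7.48 CPM in Control 1 female to 7013 CPM in Control 5 male, Apob from 9.44 to 7517 CPM, Cubn from 8.03 to 822 CPM and Apoa1 from 2.66 to 957 CPM, with Control 5 male highest in each. Alb was highest in Control 3 male, at 562 CPM, with a median of 7.11 CPM. On chromosome 12, Nemf ranged from 179 to 8446 CPM of total counts, Lrr1 from 0.697 to 1207 CPM (highest in Control 6 female) and Mgat2 from 44.8 to 830 CPM (highest in Control 1 female). These genes lie at 69310522 to 69357165, 69168814 to 69179009 and 69184157 to 69186770, between the 7SL RNA genes Rn7s1 (from 69159295) and Rn7s2 (to 69361481).

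A hypothesis is that Xist counts in libraries labelled male came from maternal decidual tissue left after dissection, which the dissection was meant to remove. Over 10 libraries labelled male, without Control 2, Xist stood at 7.45 to 34.6% of the female mean (median 11.7%) and correlated with the decidual stroma list at r = 0.965 and rho = 1 (permutation p = 1e-05, the smallest that the permutations can give, adjusted p = 0.00028 over 28 lists), with r = 0.987 without the 2 libraries farthest in the list. The hypoxia response list (r = 0.902, adjusted p = 0.00196) and the list of oxidative stress defence (r = 0.838, adjusted p = 0.0231) also passed. These lists may follow the same tissue, so r = 0.965 does not tell decidua from other maternal tissue, and a fetal source of Xist was not tested.

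The deposited comparison gave 39 genes where the litter fit by the titles gave 0. Its Wald statistic correlated across genes with the litter fit at r = 0.988 with Control 6 and EtOH 5 exchanged, the highest of 31 groupings (the next was 0.766, for Control 6 and EtOH 2), which is consistent with that comparison having used the other groups of these litters. DESeq2 on 22 placentas grouped by the titles gave r = 0.540 and 0 calls, which argues against another tool or model on the titles' groups. With the litters exchanged it called 46 genes, 37 of them among the 39, while edgeR on 22 placentas with the litters exchanged called 0 (1220 at an unadjusted p under 0.05, smallest adjusted p = 0.0809) and DESeq2 on litters called 0 (777, smallest adjusted p = 0.0982). Whether the titles or the other groups of these litters are right cannot be told apart from these expression values, because no ethanol effect is known beforehand, and 48 of 100 splits gave as many genes at an unadjusted p under 0.05 as the exchanged groups (572). Among the authors' records, the treatment row puts both litters in the other groups, against the titles. The name marks of the counts matched that row in 22 of 22 libraries. In the authors' litter row Control 1 to 5 are A to E, and EtOH 5 follows as F. Control 6 is G, followed by EtOH 1 to 4 as H to K. These records and the deposited comparison stand together against the titles, so the main ethanol results here may rest on wrong groups for both litters.

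Other splits of the same litters bear on each count. For ethanol in litters 92 of 100 splits of the 462 possible gave as many genes at an unadjusted p under 0.05 as the 212 of the real split (highest other 3749, with Control 1, 4, 5 and EtOH 1 and 3 as the set of 5, so chance cannot be excluded). As the highest of 100 it has no reference value of its own. A structure among litters other than the treatment rests on the 1940 genes that differed among litters of the same treatment by the titles. If the titles of Control 6 and EtOH 5 are wrong, part of that difference could be treatment. Chance could not be excluded for males either (100 of 100, 122 against a highest other of 3437), for females (75 of 100, 372 against 2260), for the interaction (81 of 100, 154 against 1281) or for the gene lists (88 of 100, 6 lists against 17). For the sex difference by the labels, with siblings exchanged within litters, 2 of 100 splits gave as many genes (1231), and the only higher one, with 1247, is the mirror of exchanging the labels of Control 1, 2 and 5. For this count chance is unlikely, but a draw of 100 splits cannot exclude it. Without Control 2 and Control 5 female 1 of 100, the real one, gave 24 genes past the false discovery rate, against a highest other of 0, but these libraries were left out by sex-linked genes and 21 of the 24 are sex-linked, so that count decides nothing. For autosomal genes alone in the same libraries, 1 of 100 splits, the real one, gave as many at an unadjusted p under 0.05 (1322, highest other 1214), so chance is unlikely but not excluded. Cell type lists differed between siblings, so this count does not tell a sex difference in expression from one in tissue share.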
